A study of Homo sapiens with 4 samples.

How the data were processed

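Peak lists were analysed from ChIP-seq of Flag-tagged ATOH8 and Myc-tagged TCF3 in DU145 cells, fixed with 1% formaldehyde for 10 min per the labels' protocols. The labels name 4 libraries, an immunoprecipitation and an input for each factor, with 1 library per group. One peak list was held for each immunoprecipitation, and each list was matched to its factor by name. The input libraries were not analysed here. Each list gives a chromosome, a start, an end and a score per peak, and the score is the authors' own value as deposited. The aligner, the peak caller, its threshold, the definition of the score and the use of the input are not given in the sources used here. Coordinates refer to hg38, per the submitters' processing notes, and are given as in the lists. Whether they count from 0 or 1 is not given in the sources used here.

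The lists were held in part. The ATOH8 list had 3 lines without a peak and the TCF3 list had 5, and scores jumped beside such lines, from 996 to 356 in the ATOH8 list and from 887 to 280 in the TCF3 list. Another ATOH8 jump, from 232 to 189, had no such line. Peaks of the scores between were not analysed here. Sequencing depth was not known, so intervals on shares cover the counting of peaks or genes only.

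Gene positions came from the RefSeq annotation of GRCh38.p14, whose primary chromosomes share coordinates with hg38. It gave no strand and no sequence, so the planned distance to transcription start sites was replaced by the distance from the peak midpoint to the nearer end of a protein-coding gene (19974 genes on chromosomes 1 to 22 and X). The planned searches for E-boxes and other short sequence words need the genome sequence and were not run. Peaks on other sequences were left out of the comparisons.

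Overlap meant at least 1 shared bp. Overlap and gene-end shares were set against 1000 seeded placements of each peak on its own chromosome within the span of annotated genes (one-sided). Shares have Wilson 95% intervals. Counts were compared by two-sided Fisher's exact tests, and 12 gene lists of 258 distinct genes, all found in the annotation, gave 24 tests adjusted together by the Benjamini-Hochberg method at 0.05. Differences between factors in log2 odds, with 0.5 added to each count, were set against 10000 random gene lists of the same size. Medians of scores were compared by permutation tests with 100000 resamples. The scripts were tested on simulated data: 0, 40, 200 and 1200 planted overlaps among 4000 peaks gave an excess of -3, 40, 195 and 1183. Simulated lists of 25 genes had a peak at 18, 36 and 54% of members, against 18% of other genes. A fixed threshold on the unadjusted Fisher's exact p called 1, 36.5 and 92.5% of them. The real backgrounds were 22.7% (ATOH8) and 28.5% (TCF3) and the threshold was adjusted, so these rates do not apply directly to the lists below.

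The gene lists, the main tests, the rule for named genes and most alternatives were fixed before the data were examined. The log2 odds differences between factors were not among these tests. Named genes are SCD, ATOH8 and TCF3, the 10 highest peaks per factor, the 10 best-ranked shared pairs and the 4 highest-scoring genes per list and factor. VEGFA, HIF1A, GPX4 and ACTB, named as examples of genes with both factors, were picked from the lists afterwards. FADS1, FADS2 and TUBB, named to show limits of the counts, were picked afterwards too. Some items that the rule names are not reported here. Alternatives fixed in advance were a reciprocal overlap of 50%, midpoints within 200 bp, the higher-ranked 50% of peaks by score, leaving out the top 1% of scores, placement within 100 kb, gene-end windows of 1 kb and 50 kb, gene bodies with 5 kb on each side and all annotated genes. Where a cut by rank fell among peaks of equal score, those listed first were kept. Gene-end placement, equal numbers of peaks, leaving out 1 Mb bins with 20 or more peaks, lists without SCD, the comparison with housekeeping genes and all gene families were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.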

Results

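Genome-wide binding of a pair of transcription factors was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in DU145, an established human prostate cancer cell line. ATOH8, a basic helix-loop-helix (bHLH) factor, was recovered through a Flag tag, and TCF3, a broadly expressed bHLH protein of the E protein class, through a Myc tag. Each immunoprecipitation was represented by 1 library with 1 matching input library, so there were 4 libraries in all and no replicates. The peak lists named 4997 ATOH8 peaks and 11390 TCF3 peaks, of which 4951 and 11330 lay on chromosomes 1 to 22 and X. The ATOH8 peaks had a median width of 709 bp and covered 4.06 Mb, and the TCF3 peaks had a median width of 718 bp and covered 10.6 Mb. The authors' score of a peak ran from 51 to 8846 in the ATOH8 list, with a median of 84, and from 35 to 19871 in the TCF3 list, with a median of 61. Scores were used only within a list. Read depth was not known from the peak lists, and stretches of scores between listed peaks were not analysed here, so a gene without a listed peak was not taken as unbound. All tests compared the peaks of 2 libraries, not conditions, and neither peaks nor genes are replicates.

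**Figure D1:**
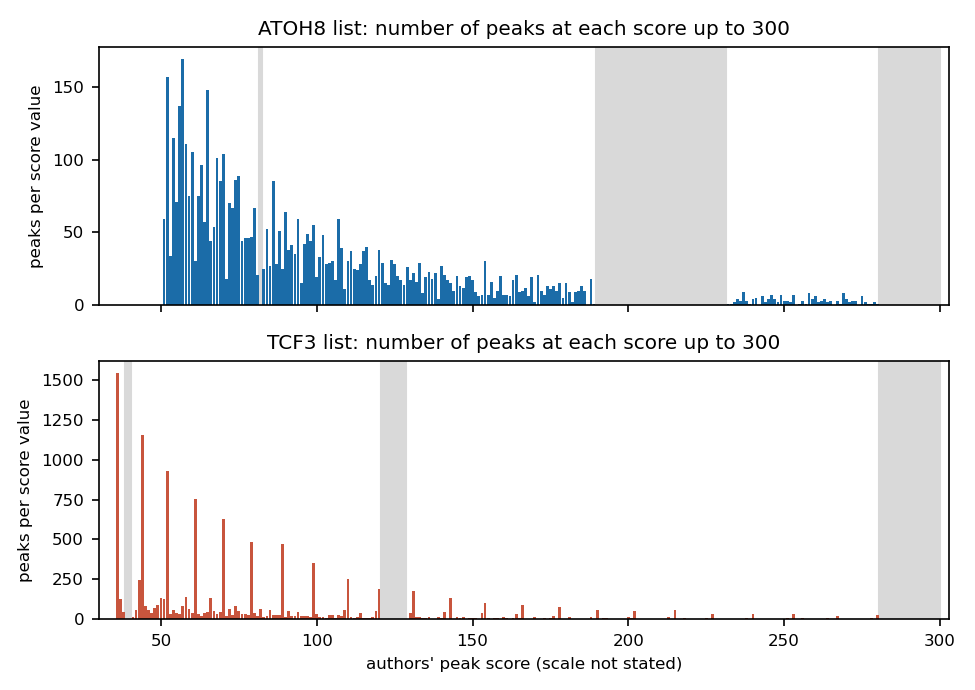
Number of peaks (vertical axis) at each value of the authors' score in its lower range (linear axis), ATOH8 above and TCF3 below, with grey bands over score ranges between listed peaks that hold none. The TCF3 scores piled up at 23 separate values holding 67.0% of its peaks.

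The title of the series names SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, so the first question was whether either factor had a peak at this gene. An ATOH8 peak lay inside SCD (chromosome 10, 100347233 to 100364826, hg38), from 100347331 to 100348476. It started 98 bp inside the lower-coordinate end of the gene. Its score of 65 was above that of 25.9% of the ATOH8 peaks. No TCF3 peak was listed within 100 kb of SCD, and the nearest began at 100115056 and ended at 100115427, 232 kb away. The ATOH8 peak at SCD shared no base with a TCF3 peak. With no replicate library, the peak has no error estimate.

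**Figure D2:**
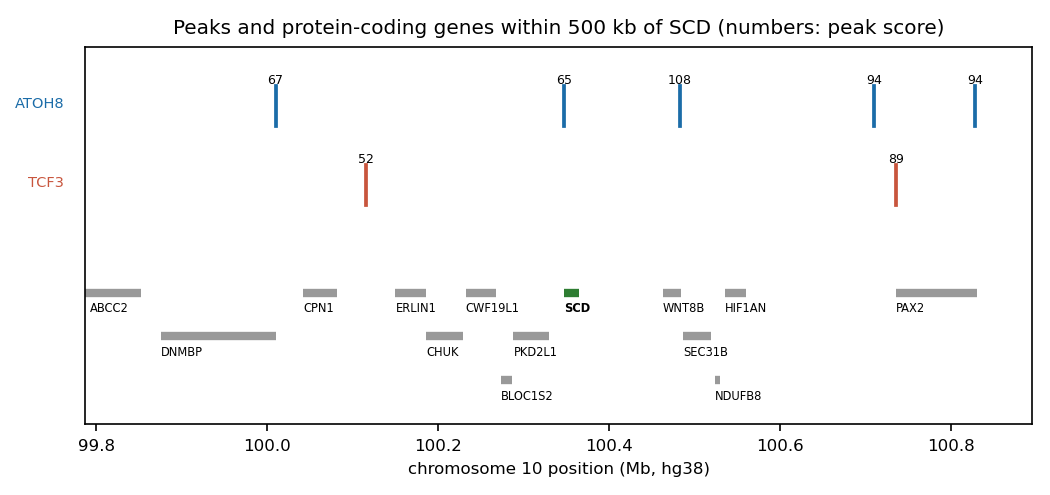
Positions of listed peaks (vertical lines at peak midpoints, numbers giving the authors' score) and of protein-coding genes (bars, SCD in green) along chromosome 10 in Mb. Within 500 kb of SCD there were 5 ATOH8 peaks and 2 TCF3 peaks, and the ATOH8 peak with score 65 lay inside SCD.

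The genes of the profiled factors were examined in the same way. The ATOH8 gene (chromosome 2, 85753991 to 85791383) held an ATOH8 peak with score 80 across its lower-coordinate end, from 85753939 to 85754820, and its nearest TCF3 peak had a midpoint 97377 bp beyond the gene. The TCF3 gene (chromosome 19, 1609292 to 1652615) held an ATOH8 peak with score 102 from 1651151 to 1652246, near its higher-coordinate end. It also held a TCF3 peak with score 47 from 1618797 to 1620278, 10246 bp from an end.

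The next comparison asked how far the peaks of the 2 factors coincided. Of 4951 ATOH8 peaks, 1425 shared at least 1 bp with a TCF3 peak (28.8%, Wilson 95% interval 27.5 to 30.1%), and 1417 of 11330 TCF3 peaks shared a base with an ATOH8 peak (12.5%, 11.9 to 13.1%). The shared pairs with the best ranks in both lists included a pair inside AKAP1, which encodes an anchor of protein kinase A, with scores 273 for ATOH8 and 202 for TCF3. Others lay inside BAZ1A, a chromatin remodelling subunit gene (180 and 260), MYO1D (326 and 166), CFL2, which encodes a cofilin (175 and 227), and MRPS30, a mitochondrial ribosomal protein gene (259 and 154). Pairs outside protein-coding genes had ZNG1F, RNF187, POTEG and ZNF777 as nearest protein-coding genes, at distances of 8716 to 135328 bp from a gene end.

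Placing the ATOH8 peaks at random on their own chromosome gave a mean overlap of 0.774%, so the observed share was 37.2 times as high (one-sided permutation test by placement, p = 0.001, the smallest that 1000 placements can give). The ratio was 4.40 when the peaks were moved to the ends of randomly drawn protein-coding genes, where 6.54% overlapped. These genes were drawn whatever their activity, so the ratio cannot separate shared binding from signal common to both libraries. TCF3 peaks that shared a base with an ATOH8 peak had a median score of 76 against 61 for the others (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The ATOH8 medians were 86 and 83 (permutation p = 0.139). Neither score comparison was adjusted for peak width or place. Shared TCF3 peaks had a median width of 803 bp against 706 bp for the others. TCF3 peaks within 1 kb of a protein-coding gene end had a median score of 70, against 52 to 61 in other places.

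The 2 lists differed in where their peaks lay relative to protein-coding genes. ATOH8 peaks had their midpoint within 5 kb of an end of such a gene in 3791 of 4951 cases (76.6%, Wilson 95% interval 75.4 to 77.7%), against 12.1% after random placement. TCF3 peaks did so in 5532 of 11330 cases (48.8%, 47.9 to 49.7%), against 11.0%. Outside protein-coding genes and beyond 5 kb from their ends lay 554 ATOH8 peaks (11.2%) and 4000 TCF3 peaks (35.3%). The ATOH8 share was higher by 27.7 percentage points (95% interval 26.2 to 29.2; odds ratio 3.43, two-sided Fisher's exact test, p = 1.81e-248). With the ends of all annotated genes, pseudogenes and non-coding genes included, the shares were 86.5% and 83.8%, and the difference fell to 2.69 points.

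**Figure D3:**
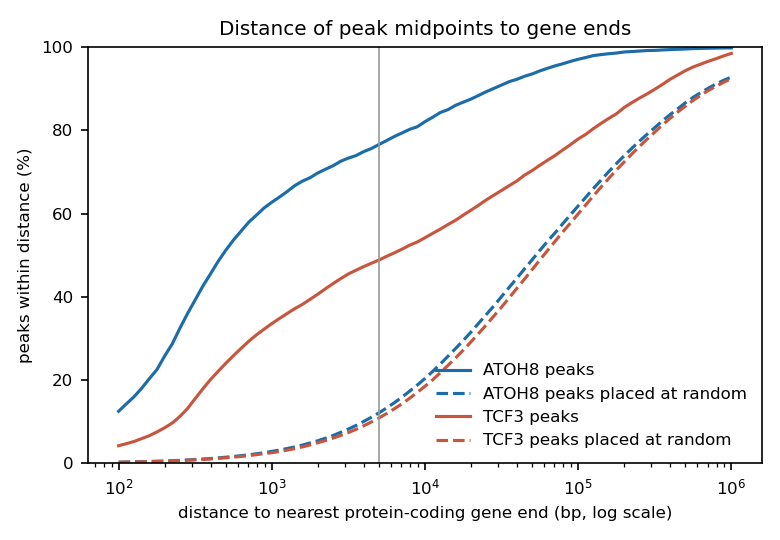
Cumulative share of peaks (%) by distance of the midpoint to the nearest end of a protein-coding gene (bp, log axis), for listed peaks (solid) and randomly placed peaks (dashed). Within 5 kb (grey line) lay 76.6% of ATOH8 peaks and 48.8% of TCF3 peaks.

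Among the highest-scoring ATOH8 peaks on these chromosomes, 4 lay together on chromosome 16 between 46386127 and 46398970, far from any protein-coding gene, with scores of 3253 to 8846. The next were inside DMPK, which encodes the myotonic dystrophy kinase (1530), EXOC6, an exocyst gene (1430), and PRR36 (1353), followed by peaks near ENTPD8 (1273), inside MRPL34 (1202) and 347 bp from the pseudogene AMZ2P1 (1180). For the 4 ATOH8 peaks on chromosome 16 the nearest annotated gene was the pseudogene ANKRD26P1, 70367 to 81034 bp away. Whether their high scores reflect binding was not tested. The highest TCF3 peaks lay in the ribosomal RNA genes RNA45SN2 (8401) and RNA45SN3 (5032) on chromosome 21. The other peaks, with scores of 1404 to 3876, had POTEG, OR11H1, RNF187, TAF11L10, TAF11L3 and OR11H12 as nearest protein-coding genes. Those at TAF11L10 and TAF11L3 had midpoints 1302 and 476 bp from a gene end. The peak nearest to RNF187 was 431 bp from the pseudogene RNA5SP19 and 61154 bp from RNF187. Peaks nearest to POTEG, OR11H1 and OR11H12 lay inside pseudogenes or a long non-coding RNA gene, 24446 to 134792 bp from those protein-coding genes.

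At the level of genes, 4543 of 19974 protein-coding genes (22.7%) had an ATOH8 peak within 5 kb of an end and 5689 (28.5%) had a TCF3 peak. Both factors were listed at 1944 genes, among them VEGFA, HIF1A, GPX4 and ACTB, where independent lists would give 1294 (ratio 1.50, odds ratio 2.33, two-sided Fisher's exact test, p = 5.16e-124).

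Gene lists were then compared, with the question of whether genes of ferroptosis, an iron-dependent cell death driven by lipid peroxidation, and of lipid synthesis carried peaks more often than other protein-coding genes. ATOH8 peaks lay at 13 of 25 ferroptosis suppressor genes, with the highest scores at GCH1 (140), which makes the cofactor tetrahydrobiopterin, GPX4 (136), the lipid peroxide reductase, HSPB1 (133) and GCLC (128), a subunit of the enzyme that starts glutathione synthesis. This was more often than at other genes (odds ratio 3.69, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0107 over 24 tests). Peaks of ATOH8 lay at 15 of 33 genes of fatty acid and sterol synthesis, the highest at ME1 (159), SREBF1 (122), which encodes a sterol-regulated transcription factor, LSS (116) and MVK (113) (odds ratio 2.84, adjusted exact p = 0.0259). In the latter list FADS1 and FADS2 had the same ATOH8 peak as their highest (score 97), so its p-value may be too small. SCD belongs to both lists and is the study's own gene. Without it the counts were 12 of 24 (odds ratio 3.40, adjusted exact p = 0.0259) and 14 of 32 (odds ratio 2.65, adjusted exact p = 0.0451).

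Hypoxia response genes carried ATOH8 peaks in 14 of 23 cases, with the highest scores at EGLN3 (164), HIF1A (159), VEGFA (152) and EPAS1 (137), genes of the oxygen-sensing pathway (odds ratio 5.30, adjusted exact p = 0.00228). Of the ID and HES genes, which encode repressors and inhibitors of bHLH factors, 9 of 16 carried one, with ID1 (329), HES1 (277), HES7 (258) and HES4 (145) highest (odds ratio 4.37, adjusted exact p = 0.0228). Ferroptosis promoter genes had ATOH8 peaks in 9 of 22 cases, among them CHAC1 (183) and POR (179) (odds ratio 2.35, adjusted exact p = 0.138), which did not pass.

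The housekeeping genes, a technical control that includes HSP90AB1 and ACTB, also had ATOH8 peaks in 9 of 22 cases (odds ratio 2.35, adjusted exact p = 0.138). None of the 4 lists that passed for ATOH8 differed from the housekeeping list by a direct test within 5 kb: ferroptosis suppressors gave an odds ratio of 1.56 (Fisher's exact p = 0.561), fatty acid and sterol synthesis 1.20 (p = 0.787), hypoxia response 2.25 (p = 0.238) and ID and HES genes 1.86 (p = 0.512). Within 1 kb the housekeeping list was at the level of other genes (4 of 22, odds ratio 1.04), while ferroptosis suppressors (13 of 25, odds ratio 5.09, adjusted exact p = 0.00114) and hypoxia response genes (12 of 23, odds ratio 5.12, adjusted exact p = 0.00136) passed. Set directly against housekeeping genes at 1 kb, these gave odds ratios of 4.88 and 4.91, neither past the adjustment (Fisher's exact p = 0.0318 and 0.0287, adjusted p = 0.350 for both). With only 22 housekeeping genes, the direct tests could miss a difference, so they do not show that the lists are alike. The 1 kb cut used midpoints and took no account of peak width. The highest ATOH8 peaks at ACTB, TUBB and YWHAZ had midpoints 1078, 1438 and 1451 bp from a gene end. The housekeeping count at 1 kb may therefore miss peaks that reach closer. Within 1 kb, fatty acid and sterol synthesis (odds ratio 2.68, adjusted exact p = 0.0577) and ID and HES genes (odds ratio 3.65, adjusted exact p = 0.0649) lost their call, though their odds ratios remained above 1. Within 50 kb all 4 lists lost it (odds ratios 2.19 to 2.79, adjusted exact p = 0.0988 to 0.270). Among the higher-ranked 50% of peaks by score, hypoxia response genes (odds ratio 3.82, adjusted exact p = 0.0274) and ID and HES genes (odds ratio 5.57, adjusted exact p = 0.0209) passed, ferroptosis suppressors (odds ratio 2.26, adjusted exact p = 0.307) and fatty acid and sterol synthesis (odds ratio 1.59, adjusted exact p = 0.574) no longer passed, and the housekeeping list did (odds ratio 4.09, adjusted exact p = 0.0266).

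TCF3 peaks lay at 17 of 27 genes for bHLH activators and E proteins, with high scores at TWIST1 (178), a mesodermal factor, TCF12 (154), another E protein, and NEUROG2 (94), a proneural factor. The list passed (odds ratio 4.28, adjusted exact p = 0.00378), while ATOH8 peaks lay at 6 of 27 of these genes, ASCL2 (171) highest (odds ratio 0.97, adjusted exact p = 1). Against the housekeeping list it did not differ for TCF3 (17 of 27 against 11 of 22, odds ratio 1.70, Fisher's exact p = 0.398, adjusted p = 0.955). The difference between the factors was 2.03 on the log2 odds scale and did not pass adjustment (permutation over 10000 random lists of the same size, p = 0.0236, adjusted p = 0.283). With equal numbers of peaks in both lists the TCF3 odds ratio was 2.04 (adjusted exact p = 0.275), and with the higher-ranked 50% of peaks it was 2.10 (adjusted exact p = 0.307).

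No other list passed for TCF3, but none of the 4 lists that passed for ATOH8 differed between the factors by permutation over random lists (adjusted p = 0.440 for hypoxia response, 0.574 for ferroptosis suppressors and for fatty acid and sterol synthesis, and 0.676 for ID and HES genes). Counts were 11 of 20 for cell cycle regulators, with CDK6 (131) and CCNE1 (110) highest (adjusted exact p = 0.0504), 11 of 23 for epithelial-mesenchymal transition (adjusted exact p = 0.138), and 11 of 23 for iron handling and BMP-SMAD signalling, where BMPR1A (240) and BMP4 (192) were highest (adjusted exact p = 0.138). The last list passed with the higher-ranked 50% of peaks (odds ratio 4.59, adjusted exact p = 0.0125), and with equal numbers of peaks it was the only list that passed for TCF3 (11 of 23, odds ratio 5.35, adjusted exact p = 0.00194). Its log2 odds difference between the factors was then 1.53 and did not pass (permutation over random lists, p = 0.140, adjusted p = 0.337). Housekeeping genes carried TCF3 peaks in 6 of 22 cases at that setting. In the iron handling and BMP-SMAD list, only TFRC and SLC40A1 among the iron genes had a TCF3 peak. The other genes with one belonged to BMP-SMAD signalling, and the 2 parts of the list were not tested apart. TCF3 peaks lay at 10 of 25 ferroptosis suppressors, MBOAT2 (120) highest (adjusted exact p = 0.354), 8 of 22 ferroptosis promoters, GLS2 (99) highest (adjusted exact p = 0.521), and 12 of 33 genes of fatty acid and sterol synthesis, led by ELOVL5 and INSIG1 (both 166; adjusted exact p = 0.424). They lay at 7 of 16 ID and HES genes, ID4 (202) highest (adjusted exact p = 0.325), 9 of 23 hypoxia response genes, VEGFA (240) highest (adjusted exact p = 0.354), and 11 of 22 housekeeping genes, ACTB (202) highest (adjusted exact p = 0.0983).

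For ATOH8 the remaining lists did not pass either: 9 of 20 cell cycle regulators, CCND3 (129) highest (adjusted exact p = 0.0981, and 0.0364 with the higher-ranked 50% of peaks), 8 of 23 epithelial-mesenchymal transition genes, DSP (180) highest, and 8 of 23 iron handling and BMP-SMAD genes, ID1 (329) highest (adjusted exact p = 0.335 for both). B and T lymphocyte targets of E proteins carried ATOH8 peaks in 2 of 18 cases, FOXO1 and PTCRA (adjusted exact p = 0.476), and TCF3 peaks in 3 of 18, IKZF1, EBF1 and FOXO1 (adjusted exact p = 0.494). Prostate luminal and basal markers carried ATOH8 peaks in 3 of 16 cases, ITGA6, FKBP5 and STEAP4 (adjusted exact p = 1), and TCF3 peaks in 2 of 16, TRIM29 among them (adjusted exact p = 0.354).

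**Figure D4:**
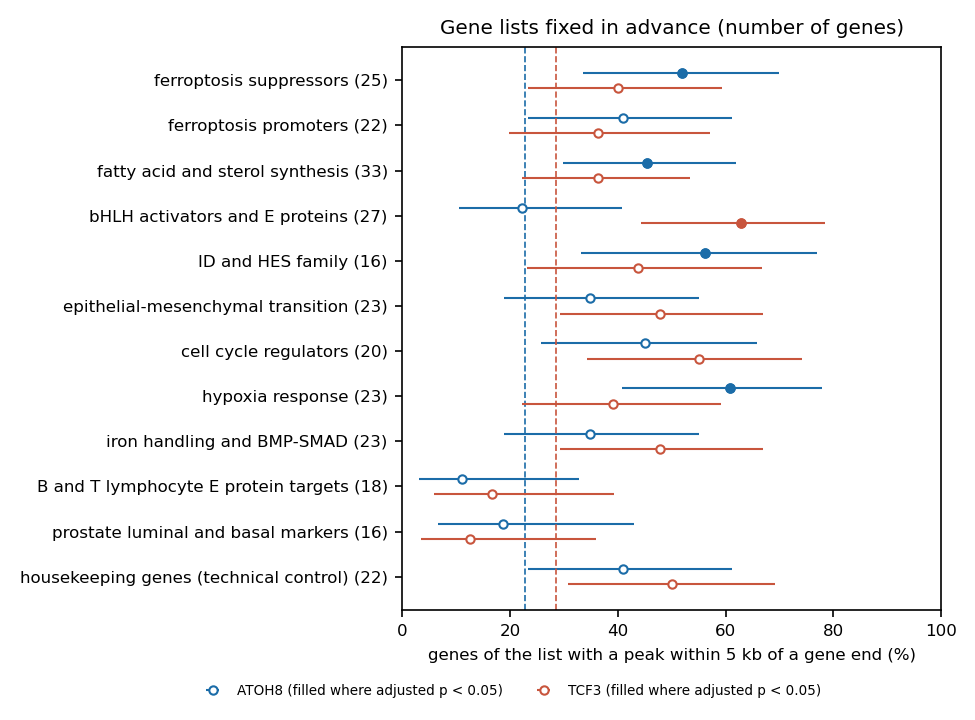
Share of each gene list (%, number of genes in brackets) with a peak within 5 kb of a gene end, with Wilson 95% intervals, for ATOH8 (blue) and TCF3 (red), and dashed lines at the shares of all protein-coding genes (22.7% and 28.5%). Filled points mark 4 lists for ATOH8 and 1 for TCF3 that passed the adjusted test against other genes, while the housekeeping list lay at 9 of 22 for ATOH8 and 11 of 22 for TCF3.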

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

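Gene families were defined after a first look at the lists, and the tests on developmental regulator genes were chosen only after the family differences were seen. Some families, such as the clustered protocadherins and the TAF11L genes, lay where TCF3 peaks were dense or highest. The family counts and p-values therefore describe these same lists and give no independent support. The tests on bHLH genes, gene ends and the highest TCF3 scores were written down before their results, but not all were left alone afterwards: the gene-end tests were set aside once seen and then reinstated, the rule for the bHLH list and list length was altered and then returned to its first form, and the pattern of highest scores was renamed. What the tRNA and pseudogene counts can decide was reconsidered after they were seen.

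Of 16 gene families tested, 8 differed between the factors in how often they carried a peak, by the difference of TCF3 and ATOH8 log2 odds over random lists of the same size. Homeobox genes, which pattern the embryo, carried TCF3 peaks in 107 of 143 cases and ATOH8 peaks in 20 (difference 3.74). SOX genes did so in 16 and 5 of 19 cases (3.20), and T-box genes in 13 and 4 of 16 (2.99). With equal numbers of peaks the T-box difference was 1.19 and no longer passed (permutation p = 0.317, adjusted p = 0.415). Clustered protocadherins, neuronal adhesion genes, had TCF3 peaks at 48 of 53 members and ATOH8 peaks at 4 (6.18). Keratin and cornified envelope genes had them at 38 and 1 of 80 (5.16), and POTE and TAF11L genes at 18 and 6 of 26 (2.35). Olfactory receptor genes had TCF3 peaks at 66 of 392 members and ATOH8 peaks at 2 (4.58), and for both factors this was below other genes. Proteasome genes went the other way, with TCF3 peaks at 5 and ATOH8 peaks at 17 of 48 members (-2.58). Among the 8 that did not pass were forkhead (1.41, adjusted permutation p = 0.0542) and GATA genes (0.41, adjusted permutation p = 0.702). Histone genes, also among these, passed towards ATOH8 with equal numbers of peaks (-1.31, permutation p = 0.0259, adjusted p = 0.0489). Neighbouring members can share peaks, so their p-values would be too small.

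Homeobox, forkhead, SOX, GATA and T-box genes together carried TCF3 peaks at 166 of 229 members, 107 of them homeobox genes, and ATOH8 peaks at 44 (difference 3.05). A longer TCF3 list was argued against as the whole cause, since with equal numbers of peaks the difference was 2.57 (permutation p = 0.0001, the smallest that 10000 random lists can give). A few gene clusters were also argued against, since over the 165 members with no other within 100 kb it was 2.70 (permutation p = 0.0001). For the bHLH list a general preference of TCF3 peaks for developmental genes may account for the excess, as those families had an odds ratio of 6.79 (adjusted Fisher's exact p = 4.15e-42), and the longer list stays open as well, since the difference went from 2.03 to 1.05 with equal numbers (permutation p = 0.299). That a factor-specific preference exists remains an untested hypothesis, because factor, tag and library cannot be separated with 1 library each.

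ATOH8 peaks lay at ends of protein-coding genes more often than TCF3 peaks. With the ends of all annotated genes the difference was only 2.69 points, and the ratios to random placement were 3.41 for ATOH8 and 3.47 for TCF3. Equal numbers of peaks were not tried with all annotated genes. The weaker peaks of the longer TCF3 list were argued against as the whole cause, because with equal numbers of peaks the difference stayed at 23.6 percentage points (Fisher's exact p = 1.90e-135). Signal at strongly transcribed genes whatever the tag stays open: tRNA genes carried ATOH8 peaks within 1 kb less often than protein-coding genes (33 of 443, odds ratio 0.377, Fisher's exact p = 1.21e-09), against the prediction, but a short tRNA gene has less room for a peak than a gene with 2 distant ends, and fewer of them carried TCF3 peaks (13 of 443, odds ratio 0.119). Housekeeping genes carried ATOH8 peaks in 4 and TCF3 peaks in 9 of 22 cases within 1 kb, and in 9 and 11 within 5 kb, while cytosolic ribosomal protein genes, also strongly transcribed, carried ATOH8 peaks within 5 kb in 19 of 80 cases (23.8% against 22.7% of other genes, odds ratio 1.06, Fisher's exact p = 0.790). A difference between the factors, tags or libraries may remain, and no test here separates them.

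Peaks outside chromosomes 1 to 22 and X numbered 46 for ATOH8 (3 on chromosome Y) and 60 for TCF3 (44 on chromosome Y) and were not part of the comparisons. They held 7 of the 20 highest ATOH8 scores and 8 of the 20 highest TCF3 scores. The sequence KI270733.1 had 9 TCF3 peaks, up to a score of 19871, and 6 ATOH8 peaks, up to 1441.

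The highest TCF3 scores lay in repeated regions such as those around POTEG and the TAF11L genes. The top 1% of TCF3 peaks (114 peaks) had a mean of 3.12 annotated pseudogenes within 100 kb against 1.91 for the rest (permutation test, p = 2e-05), which restates the pattern and measures no sharing of reads between copies, so that explanation stays open. They also overlapped an ATOH8 peak in 20.2% of cases against 12.4% (Fisher's exact test, p = 0.0214). Signal common to both libraries whatever the tag would give such an excess. Binding of both factors at the same sites would give it too, so the overlap cannot tell these apart. Peak width was not adjusted for. No biological explanation was tested.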

How the results depend on the processing

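Equal numbers of peaks, placement at gene ends, removal of dense bins, lists without SCD and tests against housekeeping genes were chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because each group held 1 library, and no count of other splits was possible for the same reason. E-box and sequence-word searches were not run without a genome sequence, nor was an alternative to the score, as the lists hold no other value. Overlap of ATOH8 with TCF3 peaks stayed above placement in 9 alternatives, at 14.9 to 33.0%. The ATOH8 excess over TCF3 at gene ends kept its direction in 6. It was 2.69 points with all annotated genes and 23.2 to 29.1 points in the others. Of 112 alternative values for single lists against other genes, 84 kept direction and side of the threshold, 11 lost the call, 4 gained it and 13 changed direction, none of these with a call; the cause was not tested. The higher-ranked 50% of peaks by score numbered 2498 for ATOH8 and 5695 for TCF3, by construction. Lists passing for ATOH8 numbered 2 at 1 kb and 0 at 50 kb, against 4, and for TCF3 0 at 50 kb, against 1. Within 500 kb of SCD lay 5 ATOH8 and 2 TCF3 peaks. Odds ratios changed direction at 1 kb for ATOH8 at bHLH (1.34), cell cycle (0.826) and prostate genes (1.08) and for TCF3 at ID and HES (0.908) and cell cycle genes (0.984); at 50 kb for TCF3 at fatty acid and sterol genes (0.836); with the higher-ranked 50% of peaks for ATOH8 at bHLH (1.24) and prostate genes (1.02) and for TCF3 at ferroptosis suppressors (0.951) and fatty acid and sterol genes (0.891); and with equal numbers for TCF3 at ferroptosis promoters (0.919), fatty acid and sterol (0.582) and hypoxia genes (0.873). Against housekeeping genes they did so for ATOH8 at 50 kb at ferroptosis suppressors (0.992), fatty acid and sterol (0.817), ID and HES (0.778) and hypoxia genes (0.875), with the higher-ranked 50% of peaks at ferroptosis suppressors (0.553), fatty acid and sterol (0.389) and hypoxia genes (0.933), and for TCF3 with equal numbers at bHLH genes (0.933).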

Other observations

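The test on score steps was chosen only after the steps were seen, as were the counts per megabase and per gene class.

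The 1 Mb bin with most TCF3 peaks, from 106000001 to 107000000 on chromosome 14 at the immunoglobulin heavy chain locus, held 110 of them and 0 protein-coding genes. V segment genes carried a TCF3 peak within 1 kb in 32 of 248 cases (12.9%) and an ATOH8 peak in 1, both less often than protein-coding genes (20.3 and 17.6%). The bin with the clustered protocadherins (chromosome 5, 141000001 to 142000000) held 50 TCF3 peaks and 64 protein-coding genes. Pseudogenes carried TCF3 peaks at 1366 (8.98%) and ATOH8 peaks at 70 (0.460%) of 15212 genes, also less often than protein-coding genes. These comparisons with protein-coding genes took no account of gene length. In both classes the share was higher for TCF3, the longer list, than for ATOH8 (0.403% of V segment genes).

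TCF3 scores fell on regular steps: 23 values from 36 to 280 held 7633 of 11390 peaks (67.0%), and the lowest step alone held 1542. The ATOH8 list had 4 such values with 130 peaks (2.60%). A candidate explanation is that many TCF3 peaks rest on whole read counts against 1 flat background. Poisson tails of counts from 7 to 29 with a mean of 1.36 met every step within 0.639 score units, with the first count, the mean and an offset fitted to the same steps. If so, many TCF3 peaks could rest on few reads, which the lists cannot show directly.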
